A study of Mus musculus with 2 samples.

How the data were processed

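Bulk RNA sequencing was done on 2 cultures of mouse skin fibroblasts, the wild-type cell line labelled MDFB, 1 given vehicle and 1 given IL-17A. Per the labels' protocols, total RNA was taken with a PureLink kit and libraries were made with Illumina's stranded mRNA preparation, which selects polyadenylated transcripts. The submitters' processing notes name STAR, featureCounts and the build mm10, and their versions, the gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are raw counts per gene symbol, as whole numbers with no normalization by the authors, 1 column per library. Levels in CPM are counts divided by the TMM-scaled library size. Total counts were 24427027 for vehicle and 23559416 for IL-17A. A count of 0 in a library allowed up to 3 counts, which, relative to the unscaled total, is 0.123 CPM with vehicle and 0.127 with IL-17A.

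Of 19674 rows, 1828 had no count in either library, and 17414 (88.5%) had a symbol found in the RefSeq annotation of GRCm38.p6, which gave gene types and coordinates. A further 21 rows carried date-like symbols of the kind spreadsheet software makes from gene names, and 2 of these symbols occurred 2 times. They held 0.275% of the vehicle counts and 0.208% of the IL-17A counts, stayed in totals and counts of genes, and were not named. Genes with near-identical copies elsewhere in the genome, such as Gapdh with 183 vehicle counts, mt-Co2 or the Saa, Gbp and H2 families, were taken as uncertain, since reads shared among copies may have been dropped or split. Genes overlapping another on the opposite strand were uncertain for want of a stated strand setting.

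The fixed design was a ratio of scaled counts without a test, because 1 library per group leaves no residual degrees of freedom for edgeR's quasi-likelihood test or DESeq2. Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3, and the ratio of IL-17A over vehicle was taken for genes with at least 50 counts summed over both libraries. Its interval was the exact 95% Clopper-Pearson interval of the IL-17A share of a gene's counts. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and leave out variation between cultures. A gene with 0 counts in a library was set to the floor of 3 counts in that library and its ratio against this floor is given together with the lower bound of its counting interval, which is the lower of the pair. A gene was called higher or lower at 2-fold or more, a rule of size that describes these libraries and not the conditions.

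The chance level of this rule came from 100 simulated pairs of libraries at the observed depths with equal expression, under Poisson counting alone and with an assumed biological coefficient of variation of 0.1 or 0.2. Poisson counting gave on average 3.45 genes higher and 3.54 lower, the assumed 0.1 gave 10.7 and 11.2, and the assumed 0.2 gave 164 and 167. The calculation was tested on simulated counts with 200 genes changed by known folds, run on 13548 genes. All 46 genes lowered 4-fold, all 50 raised 4-fold and all 50 raised 2.83-fold were recovered, along with 98.0% of 49 lowered 2.83-fold. Among 13353 unchanged genes, 5 passed 2-fold and 95.8% of intervals held the true ratio.

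The size rule, the minimum, 29 gene lists, the rule for named genes and the settings to be varied were fixed before the data were examined. The lists covered IL-17 target genes, neutrophil-attracting and other chemokines, cytokines and growth factors, NF-kB, the IL-17 receptor, acute-phase genes, prostaglandin and nitric oxide synthesis, metalloproteinases, collagen and matrix, myofibroblast genes, fibroblast identity, dermal subsets, adipocyte lineage, interferon-stimulated genes, antigen presentation, cell cycle, glycolysis and hypoxia, immediate early genes, stress responses, cholesterol synthesis, oxidative stress, markers of 5 groups of other cell types, mitochondrially encoded genes and reference genes. For each list the median log2 ratio of its measured members was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. A 95% interval of each median came from resampling its members. Genes on a list that were absent from the count table were not analysed here.

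The text names the 12 genes higher and the 12 lower whose interval had its nearer bound farthest from 1, without predicted gene models and pseudogenes. It also names every IL-17 target gene past 2-fold, up to 4 members of each other list with the highest absolute ratio, the most abundant marker of each other cell type, and always Il17ra, Il17rc, Col1a1, Col1a2, Col3a1, Vim and Pdgfra. These made 143 genes, of which 1 is not used here by name. Other genes are named only where the text says that they were chosen after their values were seen.

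The settings tried beside these were total-count, upper-quartile and DESeq2 1.42.0 median-of-ratios scaling, minimums of 10, 200 or no counts, thresholds of 1.5-fold and 3-fold, an interval beyond 1.5-fold, a prior count of 2, and a mean over list members. Added after the data were seen were a loess correction (span 0.3) for transcript length and GC content, protein-coding genes alone, lists without IL-17 target genes, and 10 further gene lists reported in the closing part, among them a wider list of imprinted genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.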

Results

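Gene expression was measured by bulk RNA sequencing in fibroblasts from mouse skin, a wild-type cell line that the labels call MDFB. The cells were given vehicle or IL-17A, an inflammatory cytokine that signals through a receptor built from Il17ra and Il17rc. Each group held 1 library, and both libraries carried the same batch label. The labels gave no dose and no length of treatment. The vehicle library held 24427027 counts over 17462 genes with a count, and the IL-17A library held 23559416 counts over 17366 genes. Of the 19674 gene rows in the count table, 13534 reached the minimum of 50 counts summed over both libraries and are called measured here. Across these genes the log2 levels of the libraries had a Pearson correlation of 0.956 and a Spearman correlation of 0.964, computed over genes, which are not independent replicates.

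The comparison concerned which transcripts differed between IL-17A-treated and vehicle-treated fibroblasts, within a series on the cells that IL-17 acts on in inflamed skin. The IL-17A library was marked by transcripts for matrix-degrading enzymes, neutrophil chemokines, acute-phase proteins and inflammatory cytokines. Mmp3, a stromelysin that cleaves extracellular matrix, was 119.7-fold (95% counting interval 112 to 128) higher, from 839 to 92420 counts. Saa3, an acute-phase serum amyloid A protein, was 37.2-fold (95% counting interval 36.0 to 38.4) higher and held 135804 counts in the IL-17A library. Lcn2, an antimicrobial protein that binds bacterial iron carriers, was 54.0-fold (95% counting interval 48.7 to 60.1) higher. Eln, which encodes elastin, was 22.2-fold (95% counting interval 19.9 to 24.9) lower, and Lgr5, a receptor for R-spondins, was 21.2-fold (95% counting interval 19.8 to 22.8) lower. In the RefSeq annotation of GRCm38.p6, the assembly also known as mm10, Saa3 lies on chromosome 7 at 46711998 to 46719615, Lcn2 on chromosome 2 at 32384637 to 32387739, Eln on chromosome 5 at 134702595 to 134747368 and Lgr5 on chromosome 10 at 115450314 to 115587780.

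Among the 12 genes that stood highest by the nearer bound of the interval, U90926 went from 7 to 3533 counts, 549-fold (95% counting interval 266 to 1365). The stromelysin Mmp10 was 372-fold (95% counting interval 208 to 746) higher, and the gelatinase Mmp9 was 41.9-fold (95% counting interval 39.0 to 45.1) higher. Cxcl2, a neutrophil chemokine, went from 7 to 1286 counts and was 199.7-fold (95% counting interval 96.6 to 498) higher. Csf3, the growth factor that drives granulocyte production, was 67.5-fold higher, the potassium channel subunit Kcnf1 56.7-fold, and Hp, the haemoglobin-binding protein haptoglobin, 45.3-fold. Il1a had no count in the vehicle library and 171 in the IL-17A library. It was 61.9-fold higher against a floor of 3 counts, and at least 49.8-fold by the lower bound of the 95% counting interval. Nos2, the inducible nitric oxide synthase, had 2 counts with vehicle and 451 with IL-17A, 245-fold (95% counting interval 67.5 to 2029.9) higher. Serpinb2, an inhibitor of plasminogen activators, had 2 and 260 counts and was 141-fold (95% counting interval 38.7 to 1173) higher.

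Among the 12 lowest genes, with Eln and Lgr5, were Chodl at 25.6-fold lower, the endothelin receptor Ednrb at 23.0-fold and the prostaglandin E receptor Ptger3 at 19.6-fold. The matrix proteins Cilp and Ogn were 19.8-fold and 16.1-fold lower. Ccn3, a matricellular protein, was 11.2-fold (95% counting interval 10.5 to 11.9) lower from 13343 vehicle counts, and the imprinted gene Mest was 11.6-fold (95% counting interval 9.85 to 13.7) lower. Angptl1 was 24.3-fold lower. Cdh8 had 105 counts with vehicle and 2 with IL-17A, and Gpr17 had 61 and 1, with intervals of 13.0 to 404 and 9.70 to 2253 for the fold lower. Genes with 1 or 2 counts in a library carried wide intervals, and adding a prior count of 2 moved the log2 ratio of Nos2 from 7.94 to 6.91, of Serpinb2 from 7.14 to 6.12, of Csf2 from 6.66 to 5.06, of Cdh8 from -5.59 to -4.65 and of Gpr17 from -5.81 to -4.31.

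In all, 702 measured genes (5.19%) were at least 2-fold higher in the IL-17A library, 500 (3.69%) were at least 2-fold lower, and 12332 lay within 2-fold. At least 10-fold differences were found for 79 genes higher and 31 lower. In 100 simulated pairs of libraries with no treatment effect, counting noise alone gave at most 11 genes higher and 8 lower. An assumed biological coefficient of variation of 0.1 gave at most 20 and 25, and one of 0.2 gave at most 196 and 200. These coefficients were not measured, the counts rose steeply between them, and larger ones were not simulated. The simulation therefore cannot show that 702 and 500 exceed the variation between cultures. With 1 library per group the differences had no replicate check and no p-value, and the intervals covered counting error only. The counts depended on where the limits were set: with a minimum of 10 summed counts they were 1090 and 955, with no minimum 1573 and 1335, at 1.5-fold 1364 and 1117, and at 3-fold 340 and 219, while a minimum of 200 left 275 lower.

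**Figure D1:**
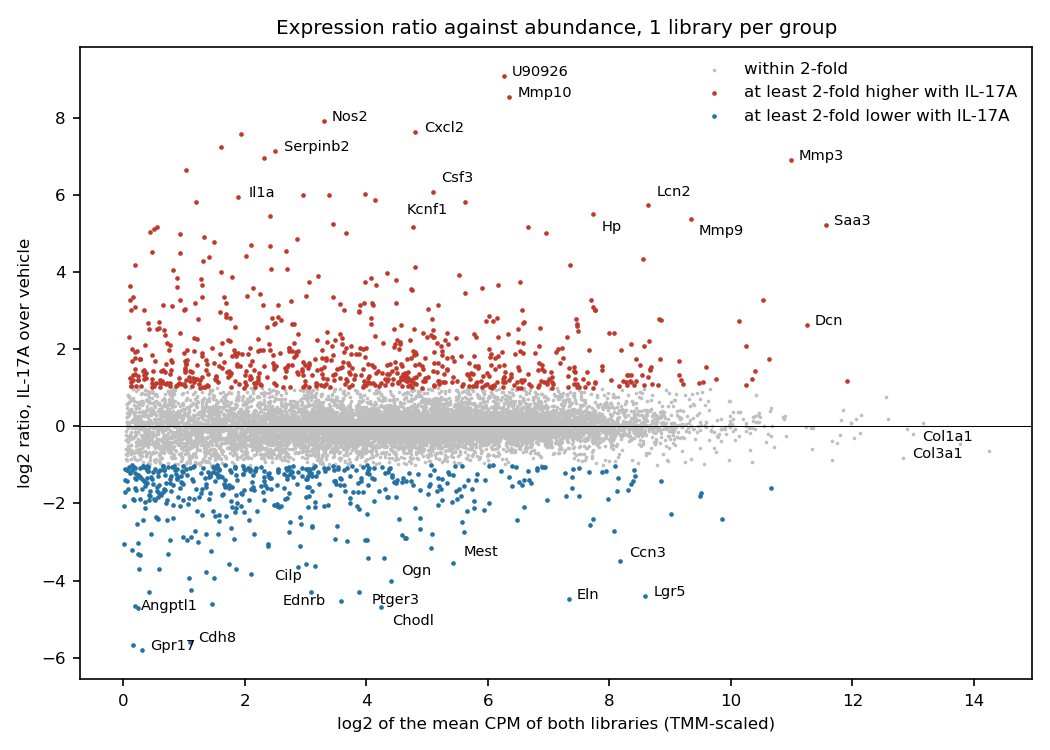
Each point is 1 measured gene, with the log2 of its mean TMM-scaled CPM over both libraries on the x axis and the log2 ratio of IL-17A over vehicle on the y axis; red points are at least 2-fold higher with IL-17A, blue points at least 2-fold lower and grey points within 2-fold. Mmp3 at 6.90 and Saa3 at 5.22 lie far above 0 among the abundant transcripts, Eln at -4.47 and Lgr5 at -4.41 far below it, and Il1a, with no vehicle count, is drawn at its ratio against the floor of 3 counts.

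The known targets of IL-17 were higher as a group. Of the 31 measured members of the list of IL-17 target genes, 29 were at least 2-fold higher and 0 were lower, with a median log2 ratio of 3.29, above all of 10000 random lists matched on expression. The other 2, the transcriptional regulators Nfkbiz and Cebpb, chosen after their values were seen, stood at 0.98 and 0.88. The summed level of all 34 genes on the list in CPM, counts scaled to the library size, was 1748 with vehicle and 21265 with IL-17A. The 3 members that were not measured were S100a8, S100a9 and Il1b, named after their values were seen. They were under the minimum, at 2, 2 and 0 counts with vehicle and 11, 2 and 43 with IL-17A. Members included Slpi, an antimicrobial protease inhibitor, at 4.84-fold higher, Tnfsf11 at 2.45-fold, the metalloreductase Steap4 at 5.90-fold, and Tnfaip2 at 3.37-fold. Of the 34 genes on this list, 33 also stood on another list, so the counts of the lists that follow are not independent of it.

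**Figure D2:**
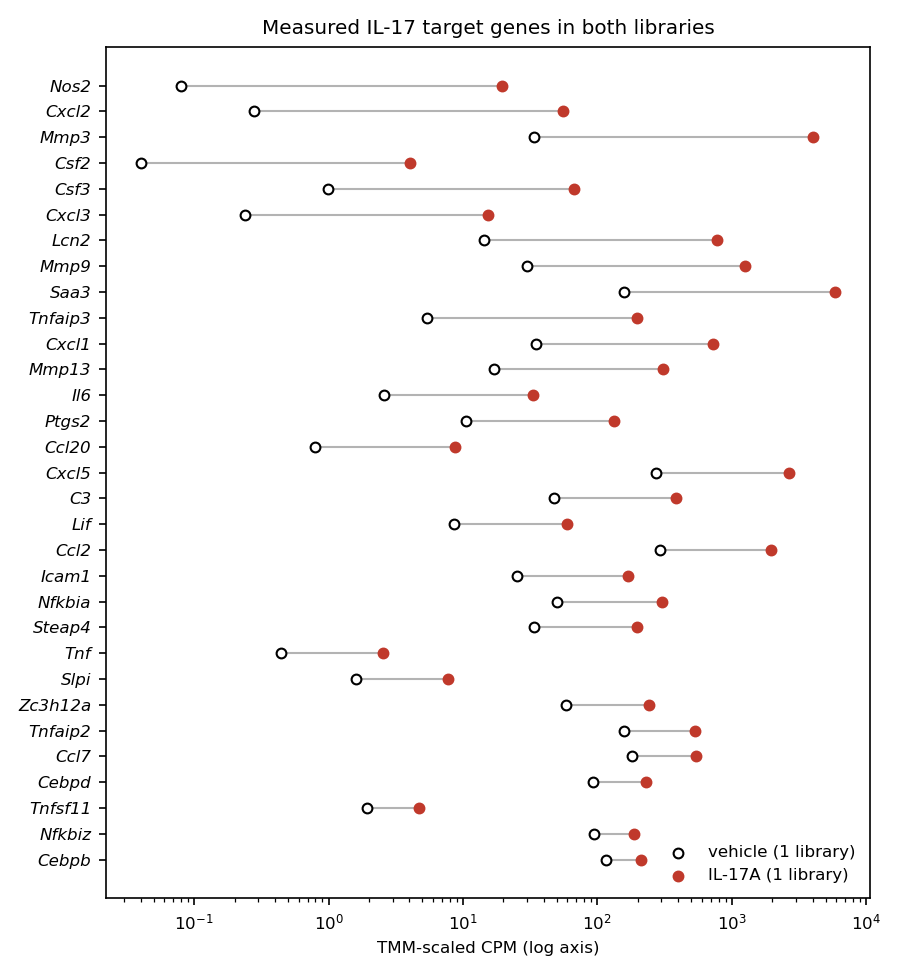
TMM-scaled CPM (x axis, log scale) of the 31 measured IL-17 target genes (y axis), with an open circle for the vehicle library and a red circle for the IL-17A library, 1 library each. Each red circle lies to the right of its open circle, from Nos2 at 245-fold down to Cebpb at 1.85-fold.

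All 4 measured neutrophil-attracting chemokines were at least 2-fold higher, with a median log2 ratio of 5.17, above every matched random list. Cxcl1 was 20.5-fold (95% counting interval 19.1 to 21.9) higher, Cxcl5 9.80-fold and Cxcl3 63.8-fold, from 6 to 352 counts. With a minimum of 10 counts, which added 1 member, the median was 4.51. These genes lie together on chromosome 5, Cxcl5 at 90759298 to 90761625, Cxcl3 at 90786101 to 90788093, Cxcl1 at 90891245 to 90893121 and Cxcl2 at 90903899 to 90905938. Of the 19 other chemokines measured, 14 were higher and 0 lower, with a median of 1.72, above all random lists. Cxcl16 was 32.3-fold higher, Ccl5 23.7-fold, Ccl6 14.4-fold and Ccl20, which attracts CCR6-bearing lymphocytes, 10.9-fold, while the monocyte chemokines Ccl2 and Ccl7 were 6.68-fold and 3.03-fold higher. A minimum of 200 counts, which left 13 of these chemokines, gave a median of 2.74.

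Of 26 cytokines and growth factors, 14 were at least 2-fold higher and 3 were lower, with a median of 1.11, above all random lists. Il6 was 12.8-fold (95% counting interval 9.91 to 16.7) higher, Lif 6.90-fold and Tnf 5.83-fold, and Csf2, with 1 count with vehicle and 93 with IL-17A, was 101-fold (95% counting interval 17.7 to 4035) higher. The 3 lower members were the alarmin Il33 at 7.66-fold, the growth factor Tgfb2 at 3.27-fold and Bmp4, from 98 to 45 counts, named after their values were seen. Without the members shared with the IL-17 target list, the medians were 1.67 for 16 other chemokines and 0.84 for 20 cytokines and growth factors, each still above all random lists.

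Of 20 genes of the NF-kB pathway and its feedback inhibitors, 11 were at least 2-fold higher and 0 lower, with a median of 1.28, above all random lists. Tnfaip3, a deubiquitinase that restrains NF-kB, was 36.4-fold (95% counting interval 30.7 to 43.5) higher, the adaptor Traf1 27.4-fold, and the inhibitors Nfkbie, Tnip1 and Nfkbia 11.5-fold, 8.18-fold and 6.07-fold. Zc3h12a, an RNase that limits inflammatory transcripts, was 4.12-fold higher. The 16 members outside the IL-17 target list had a median of 0.99, still above all random lists. The receptor genes themselves differed little, Il17ra at -0.02 (interval -0.11 to 0.07) and Il17rc at -0.00 (interval -0.13 to 0.12) on the log2 scale. Among 23 genes of the receptor and its proximal signalling, 1 was at least 2-fold higher, the kinase Ikbkb at 2.30-fold, and Traf3, Arid5a and the adaptor Traf3ip2 stood at 0.81, 0.72 and 0.71 on the log2 scale. Their median of 0.18 lay above 99.3% of random lists.

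Acute-phase, complement and antimicrobial genes were higher in 13 of 20 cases and lower in 0, with a median of 2.42, above all random lists. The complement factors Cfb and C3 were 64.4-fold and 8.16-fold higher. Outside the IL-17 target list, 8 of 15 were higher and the median was 1.24, still above all random lists. In prostaglandin and nitric oxide synthesis, 4 of 8 genes were higher and 0 lower, namely Nos2, the inducible cyclooxygenase Ptgs2 at 12.7-fold (95% counting interval 11.2 to 14.5), the prostaglandin E synthase Ptges at 9.74-fold and the phospholipase Pla2g4a at 4.01-fold. This list's median of 1.26 lay above all random lists, its mean was 2.13, and its median was 0.42 without Nos2 and Ptgs2 and 0.51 with a minimum of 10 counts.

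Of 24 matrix metalloproteinases, related proteases and inhibitors, 11 were higher and 3 were lower. Mmp13, a collagenase, was 18.3-fold (95% counting interval 16.6 to 20.2) higher. On chromosome 9 of GRCm38.p6, Mmp13 lies at 7272514 to 7283333, Mmp3 at 7445822 to 7455975 and Mmp10 at 7502342 to 7510242, and Mmp9 is on chromosome 2 at 164940326 to 164955850. The 3 lower members, named after their values were seen, were the metalloproteinase inhibitor Timp3 at 3.30-fold and the aggrecanases Adamts1 at 3.20-fold and Adamts5 at 2.54-fold. The median of 0.61 lay above all random lists with a mean of 1.43, and without the IL-17 target genes it was 0.35, above 99.98% of them.

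Collagen and matrix genes went both ways, 24 of 40 below 0 and 16 above. The abundant collagens Col1a1, Col1a2 and Col3a1 were 1.56-fold, 1.37-fold and 1.77-fold lower, inside the 2-fold limit, and Col1a1 with Col1a2 took 4.08% of all counts with vehicle and 2.63% with IL-17A. On the list, 5 genes were at least 2-fold lower and 4 higher, and the median of -0.19 lay below all random lists, with a resampled interval over members of -0.44 to 0.12 that spanned 0. After Eln, the microfibril gene Fbn2 was 6.58-fold (95% counting interval 6.25 to 6.93) lower and Col15a1 4.35-fold lower, whereas the proteoglycan Dcn was 6.15-fold (95% counting interval 6.05 to 6.25) higher. The rest past 2-fold, chosen after their values were seen, were Col6a3 and Col8a1 at -1.61 and -1.21 and P4ha2, Col5a3 and Thbs2 at 1.53, 1.21 and 1.17. Of 21 myofibroblast and TGF-beta response genes, 4 were higher and 2 lower, with a median of 0.25, above 99.2% of random lists. The higher members included Skil at 2.28-fold, Smad7 at 2.26-fold and Inhba at 2.18-fold, and the 2 lower, named after their values were seen, were the smooth-muscle genes Actg2 at 2.14-fold lower and Cnn1 at 2.07-fold lower.

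Fibroblast identity genes showed no common direction, with 3 of 18 higher, 1 lower and a median of -0.03 against a mean of 0.07, at percentile 23.4. Pdgfra stood at -0.06 and Vim at -0.59 on the log2 scale, Twist2 was 2.23-fold higher, and Fap was 2.33-fold lower. En1 was 2.02-fold higher, and its log2 ratio was 0.95 under total-count scaling and 0.98 under upper-quartile scaling, inside the 2-fold limit. Of 18 dermal fibroblast subset genes, 2 were higher and 6 lower, with a median of -0.19, at percentile 0.960 of the random lists. Prdm1, a transcription factor used to mark papillary fibroblasts, was 11.1-fold (95% counting interval 9.57 to 12.8) higher, and the surface markers Ly6c1 and Ly6a were 6.38-fold and 3.50-fold lower. Coch, the other higher member, was chosen after its value was seen and stood at 1.53. Of 12 adipocyte lineage genes, 3 were higher and 3 lower. Pparg and Cebpa, the central adipogenic transcription factors, were 5.58-fold and 2.33-fold lower, whereas the adhesion molecule Icam1 and Cebpd, both also IL-17 target genes, were 6.60-fold and 2.47-fold higher. The others past 2-fold, chosen after their values were seen, were Cd36 at -1.09 and Fabp4 at 1.03, which was inside the 2-fold limit at 0.96 under total-count and 0.99 under upper-quartile scaling. The adipocyte median of 0.39 turned to -0.92 without the 3 members shared with the IL-17 target list, below all random lists, and to the same value with a minimum of 10 counts.

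Antigen presentation and adhesion genes were higher in 10 of 16 cases and lower in 0, with a median of 1.11, above all random lists. Cd274, which encodes the checkpoint ligand PD-L1, was 6.32-fold higher, Cd40 4.39-fold and Tapbp, a peptide-loading chaperone, 3.97-fold. Interferon-stimulated genes had no common direction, with 6 of 34 higher, 3 lower, a median of -0.01 and a mean of 0.24, at percentile 48.2. The guanylate-binding protein Gbp5 was 21.2-fold higher, Irf1 3.56-fold and Ifi47 3.44-fold, and Gbp2 stood at a log2 ratio of 3.58. The 3 lower members were Usp18, Oas2 and Oasl1 at -1.52, -1.43 and -1.14, chosen after their values were seen. Minimums of 10 and 200 counts gave interferon medians of 0.04 and 0.01.

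Of 36 cell-cycle genes, 1 was at least 2-fold lower and 35 lay within 2-fold, all 36 with a log2 ratio below 0 and a median of -0.40, below all random lists. Ccnd1, which encodes cyclin D1, was the 1 member past the limit, 3.50-fold (95% counting interval 3.32 to 3.69) lower, while Tk1, Mki67 and Mcm2 stood at -0.85, -0.71 and -0.67. Cholesterol synthesis genes were below 0 in 20 of 21 cases, with a median of -0.59, below all random lists, and 0 reached 2-fold. Hmgcs1, Sqle, Dhcr7 and Cyp51, enzymes of the pathway, stood at -0.88, -0.80, -0.78 and -0.73. Glycolysis and hypoxia genes were above 0 in 27 of 28 cases, 6 of them by at least 2-fold, with a median of 0.63, above all random lists. The vasodilator peptide gene Adm was 8.51-fold (95% counting interval 7.99 to 9.06) higher, the prolyl hydroxylase Egln3 5.19-fold, Bnip3 2.78-fold and the lactate transporter Slc16a3 2.72-fold.

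Immediate early genes went both ways, 7 of 28 higher and 3 lower, with a median of 0.20, above 99.5% of random lists. Ier3 and Maff were 3.76-fold and 2.95-fold higher, and Dusp5 and Klf4 were 3.14-fold and 2.85-fold lower, as was Egr3, chosen after its value was seen, at 2.02-fold. Among 24 genes of the integrated stress and unfolded protein response, 2 were lower and 0 higher, with a median of -0.03 at percentile 23.5. The amino acid transporter Slc7a5 was 2.18-fold lower and Trib3 2.07-fold, and the transcription factors Ddit3 and Atf5 stood at -0.75 and -0.57. Of 17 oxidative stress response genes, 4 were higher and 1 lower, with a median of 0.32, above 99.8% of random lists. The mitochondrial superoxide dismutase Sod2 was 6.73-fold higher, the metallothionein Mt2 3.85-fold, Gstm1 2.49-fold and Mt1, chosen after its value was seen, 2.21-fold, while Gsta4 was 4.08-fold lower from 71 counts.

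Many markers of other cell types were under the minimum. Of 15 keratinocyte markers 4 were measured, with a median of -0.45 at percentile 11.6. Itga6, the most abundant, stood at -0.64, Sfn was 2.06-fold lower, and the keratins Krt17 and Krt10 had 30 and 28 vehicle counts with intervals of the ratio spanning 1. Of 24 leukocyte and macrophage markers 13 were measured, of which 4 were lower and 0 higher, with a median of -0.07 at percentile 33.9 and a mean of -0.41. The complement genes C1qc, C1qa and C1qb, which are expressed by macrophages, were 4.27-fold (95% counting interval 3.34 to 5.53), 3.57-fold and 3.17-fold lower, Lck was 2.07-fold lower from 45 counts, and Lyz2, the most abundant member, stood at 0.57. Of 12 endothelial markers 5 were measured, among which Tek went from 49 to 18 counts, a log2 ratio of -1.32, and the intervals of Cdh5, Egfl7 and Prox1 spanned no difference. The endothelial median of 0.02 (percentile 58.9) was -0.05 under total-count scaling and -0.02 under upper-quartile scaling, and the mean was -0.12.

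The list of mural, Schwann and melanocyte markers had the lowest median of the 29 lists, -1.13, below all random lists, with 10 of 18 measured, 5 of these at least 2-fold lower and 0 higher. The 5 were the mural and smooth-muscle markers Kcnj8 at 15.3-fold (95% counting interval 6.80 to 42.8), Abcc9 at 13.0-fold, Myh11 at 7.50-fold, Notch3 at 3.81-fold and Cspg4, the most abundant, at a log2 ratio of -1.32. Of 5 skeletal muscle markers 0 passed 2-fold. Their median was 0.21 (percentile 83.4) with a mean of -0.06, and it was -0.62 over the 2 members with at least 200 counts. Acta1, the most abundant, stood at -0.59, Myh3 at -0.64, and Tnnt3 and Mymk at 0.36 and 0.35 with intervals spanning 0. Mitochondrially encoded genes took 0.688% of the vehicle counts and 0.637% of the IL-17A counts. Their median over 10 genes was -0.03 with a mean of 0.07, at percentile 39.9, with mt-Nd4 at -0.13 and mt-Nd6, mt-Co2 and mt-Co3 at 0.24, 0.42 and 0.39 from 139, 48 and 64 vehicle counts. Against these, mt-Co1, named after its value was seen, had 64691 vehicle counts. Reads shared with copies elsewhere in the genome may have been dropped or split, so the mitochondrial shares and median are uncertain. Of 14 reference genes 0 passed 2-fold, with a median of 0.12 at percentile 85.8, and the widest were B2m at 0.83, Tubb5 at -0.40, Gusb at 0.38 and Gapdh at 0.35.

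Some lists whose medians lay outside the central 95% of random lists had members that went both ways, so that the interval of the median over resampled members reached 0 or beyond. Besides collagen and matrix genes, these were the metalloproteinase list (-0.02 to 1.49), prostaglandin and nitric oxide synthesis (-0.27 to 3.67) and the receptor with its proximal signalling (-0.00 to 0.39). The same held for myofibroblast genes (-0.29 to 0.82), dermal subset genes (-1.13 to 0.65) and adipocyte lineage genes (-1.02 to 0.96). It also held for immediate early genes (-0.05 to 0.51) and oxidative stress response genes (-0.12 to 0.50).

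**Figure D3:**
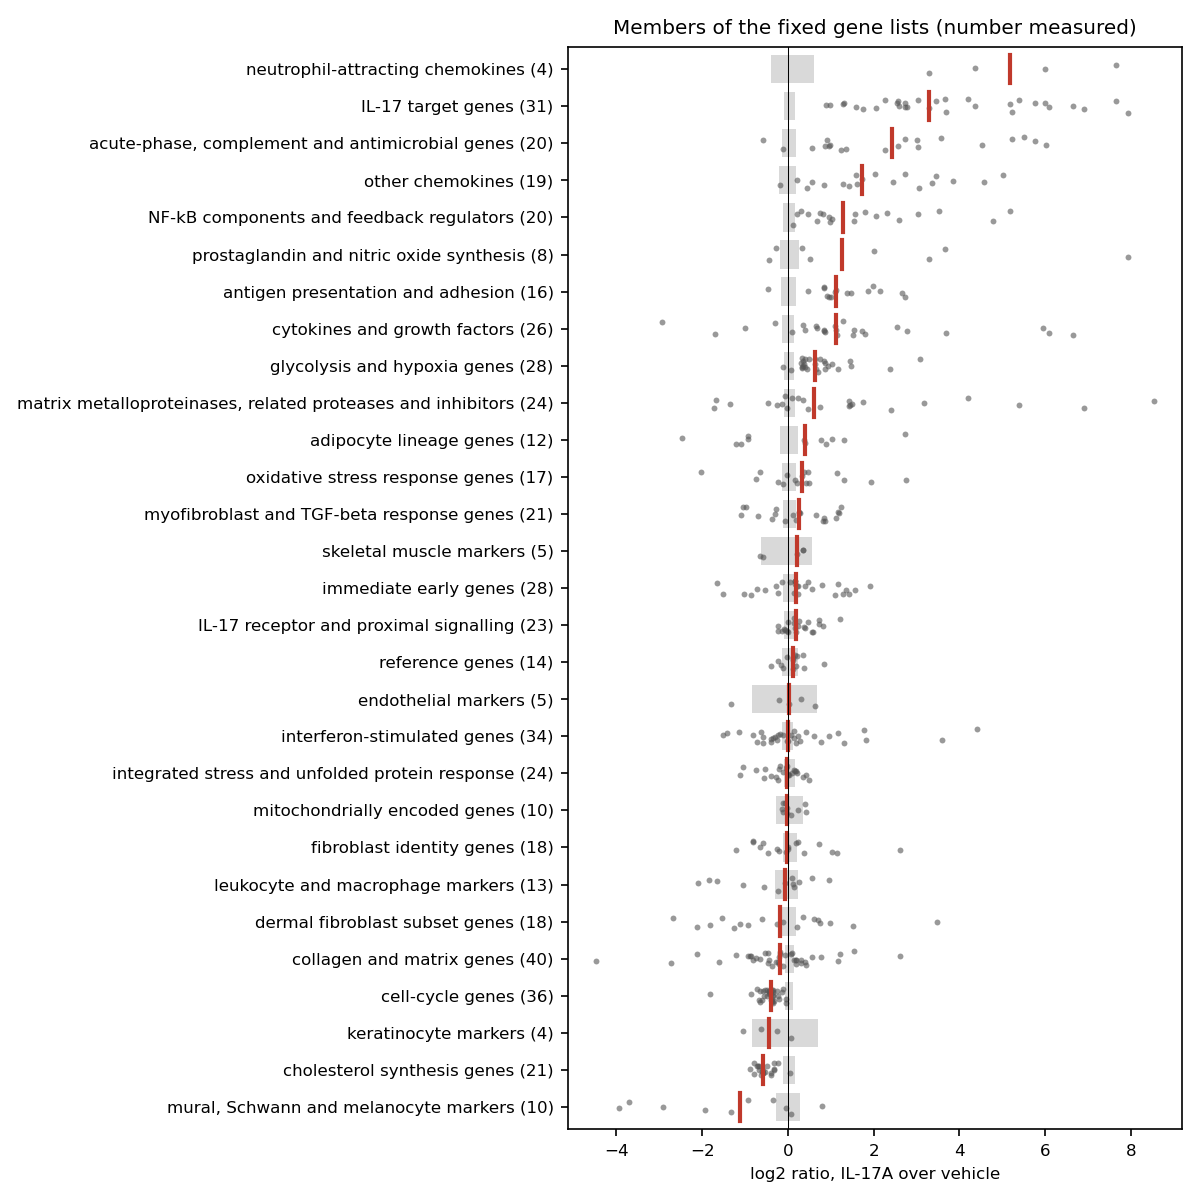
Log2 ratio of IL-17A over vehicle (x axis) for the measured members of each of 29 gene lists (y axis, number measured in parentheses), 1 library per group; grey points are genes, red bars are list medians, and grey bands hold the central 95% of 10000 expression-matched random medians. Neutrophil-attracting chemokines lie at the top with a median of 5.17, IL-17 target genes follow at 3.29, and the mural, Schwann and melanocyte markers lie at the bottom at -1.13.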

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

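The settings that left out IL-17 target genes, subtracted a length and GC trend or kept protein-coding genes alone were chosen after the result was seen. The counts of 702 genes higher and 500 lower stayed within 1.5 times under total-count scaling (644 and 552), upper-quartile scaling (666 and 533), median-of-ratios scaling (698 and 500), an interval beyond 1.5-fold (652 and 429), a prior count of 2 (684 and 478), the length and GC correction (698 and 500) and protein-coding genes alone (639 and 470). They moved further with the limits, since these change which genes are tested or pass: 1090 and 955 at a minimum of 10 counts, 1573 and 1335 with no minimum, 1364 and 1117 at 1.5-fold and 340 and 219 at 3-fold. A minimum of 200 counts left 507 higher and 275 lower. The median of the IL-17 target genes ranged from 3.22 to 3.37 over the other scalings, minimums and the length and GC correction, against 3.29, and their mean was 3.76. The adipocyte median of 0.39 reversed to -0.92 at a minimum of 10 counts, which added 3 members, and to -0.92 without the IL-17 target genes. Of 572 values for named genes under the scalings and the prior count, 535 stayed inside the counting interval, 37 left it, and 0 changed the sign of a gene past 2-fold. Of 105 named genes past 2-fold, 104 remained so under total-count and upper-quartile scaling, En1 being the exception. Other list members, named after their values were seen, also crossed 2-fold. Fabp4, Nfkb1, Psmb9 and Ankrd37 were no longer past it under both of these scalings, Itga11 was newly past it under both, and Zfp423 and Mcam were newly past it under total-count scaling. Of 210 values for list medians, 156 stayed inside the counting interval. A sign opposite to the main median was found for 12 of the 210, from 6 lists. Of these, 2 were the adipocyte values, whose main median lay outside the central 95% of random lists, and 10 belonged to the fibroblast identity, interferon, endothelial, skeletal muscle and mitochondrial lists, whose main medians lay inside it. No paired analysis was possible because each group held 1 library. Depth limited the genes under 50 summed counts, and in the absence of replicates no setting could show variation between cultures.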

Other observations

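All gene lists in this part were drawn up after the main results had been seen, and the tests of the scaling, of the number of libraries and of the summed C1q counts were chosen after their results were seen. Genes named in this part and not in the report were chosen after their values were seen. Iron handling genes were higher in 8 of 17 cases and lower in 1, with a median log2 ratio of 0.81, above all of 10000 matched random lists. Fth1, the ferritin heavy chain, was 3.35-fold (95% counting interval 3.30 to 3.41) higher, the iron carrier transferrin (Trf) 9.06-fold and the ferroxidase Cp 6.68-fold, whereas the iron exporter Slc40a1 was 8.25-fold (95% counting interval 5.49 to 12.9) lower. Pattern-recognition receptor and inflammasome genes were higher in 12 of 26 cases and lower in 0, with a median of 0.95, above all random lists. Nod2 was 25.9-fold (95% counting interval 12.9 to 61.0) higher from 8 vehicle counts, and Nlrp3 17.0-fold (95% counting interval 10.1 to 30.8) from 15. Tlr2 was 8.09-fold higher and Irak3, which restrains Toll-like receptor signalling, 6.71-fold. Bulk counts did not show which cells of the cultures held these transcripts. Since these lists were drawn up after some of their members had stood out, their positions are not independent evidence, and Lcn2 and Steap4 of the iron list are also IL-17 target genes.

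Genes of the insulin-like growth factor axis were lower in 6 of 16 cases and higher in 1, with a median of -0.47, below all random lists, and a resampled interval over members of -1.53 to 0.17. Igf1 was 3.06-fold (95% counting interval 2.79 to 3.36) lower and the adaptor Irs1 4.12-fold, and Igfbp7, the 1 higher member, stood at 1.08, while the abundant binding proteins Igfbp5 and Igfbp3 stood at -0.01 and 0.17, and the summed level of the axis was 3532 CPM with vehicle and 4207 with IL-17A. Of 21 elastic fibre genes, 4 were lower and 1 higher, with a median of -0.20, at percentile 0.0550. Beside Eln and Fbn2, the lower members were Efemp1 at 3.56-fold and Ltbp1 at 2.06-fold, whereas Emilin1 was 2.11-fold higher and Fbln5 stood at -0.28. The growth factor axis and elastic fibre lists were drawn up after the main results had been seen, Eln and Fbn2 among them. The positions of both lists are therefore not independent evidence. In the metalloproteinase region of chromosome 9 (GRCm38.p6), Mmp13, Mmp12, Mmp1b, Mmp3, Mmp10 and Mmp8, which lie between 7272514 and 7568486, had log2 ratios from 2.40 to 8.54. The flanking genes Dcun1d5 and Mmp27 stood at 0.29 and 0.21, and the next measured genes Tmem123, Birc2 and Birc3 at 0.42, 0.82 and 2.31. Xist had 2957 counts with vehicle and 2138 with IL-17A, and the Y-linked gene Ddx3y had 1409 and 1220.

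The higher IL-17 target genes were set against 3 technical explanations. A trend with transcript length and GC content was argued against by size alone. Over 13366 genes the log2 ratio had a Pearson correlation of -0.043 with log2 length and of -0.016 with GC content. Subtracting so weak a trend left the median of 31 genes, all of which had a length, at 3.27, an outcome largely set by its size. A few abundant genes shifting the scaling was argued against by size alone, since total-count scaling, the farthest from TMM, moved every log2 ratio by -0.068. Shifts this small left the lowest median over the 4 scalings at 3.22, an outcome that was fixed once they were known. A difference between the cultures other than the treatment stays open, because there was 1 library per group. The biological explanation, the IL-17A treatment that the labels name, cannot be told apart from such a difference.

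The C1q genes were lower with IL-17A. Counting noise was argued against by their summed counts, 1003 with vehicle and 254 with IL-17A, a log2 ratio of -1.86 with an interval of -2.07 to -1.66. Fewer macrophages as the whole cause would have lowered 24 other leukocyte and myeloid genes. Their median was 0.20 with a resampled interval over members of -0.04 to 0.50, with Ncf4 and Cybb at 1.86 and 1.58 and Pld4 at -1.06. Among them Mpeg1 and Ctss had 17.2 and 15.7 CPM with vehicle and 17.0 and 14.4 with IL-17A. These values argue against fewer macrophages only if the 24 genes came from macrophages and kept their level per cell. How many of the 24 fibroblasts also express, and whether levels per cell changed, was not determined. A change of state in a small number of macrophages may remain as a hypothesis. Cx3cr1 and Fcrls were 7.77-fold and 8.05-fold lower and Clec4e and Clec7a 10.2-fold and 9.66-fold higher, 4 genes chosen after their values were seen.

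The mural markers Kcnj8, Abcc9, Myh11, Notch3 and Cspg4 were lower with IL-17A. Fewer mural cells in the IL-17A culture would have lowered 14 further mural genes alike only if mural cells were their source and levels per cell held. How many of the 14 fibroblasts also express, and whether levels per cell changed, was not determined, so a median near 0 says little about mural cell number. The median of the 14 was -0.14 with a resampled interval of -0.69 to -0.07, at percentile 9.84. This interval reaches past the bound of -0.5 set for excluding the explanation, so it stays open. Among the 14, Ebf2, Kcnab1 and Gucy1b1 were at least 2-fold lower, at -1.97, -1.27 and -1.19, and Tbx18 was 2.11-fold higher. A lower expression of these genes within the fibroblasts is a candidate explanation that bulk counts could not separate from it.

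A hypothesis of lower expression across imprinted genes was formed from Mest, H19, Igf2, Dlk1, Cdkn1c, Plagl1, Zim1 and Meg3, which were picked because each was at least 2-fold lower and had a median of -1.93. On 23 imprinted genes listed before their values were seen, 3 were lower (Peg3, Mirg and Slc38a4) and 0 higher, the median was -0.16, and its percentile of 3.07 missed the 2.5 that the hypothesis required. Whether any of the 23, such as Mirg and Peg3, share an imprinted cluster with the 8 picked genes was not examined, so this list may not be independent of them. The interval over members, -0.71 to -0.08, reached well below the lower limit of random lists at -0.17, so the hypothesis stays open. The test was first written to count any percentile above 2.5 against the hypothesis, and this reading was changed to allow for the spread of the members after the value was seen. The 34 measured genes that joined these 23 to the 8 picked as lower and to Calcr, Tfpi2 and Dcn, seen higher, had a median of -0.50 and a mean of -0.32, which decides nothing, since 8 of the 11 lower and all 3 higher were fixed by the way they were picked. Several of these genes overlap others, and their counts are uncertain without a stated strand setting.

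A hypothesis of lower Wnt target expression was formed from Lgr5, 21.2-fold lower, and the Wnt inhibitor Dkk1. Dkk1 had 0 counts with vehicle and 88 with IL-17A. It was 31.9-fold higher against the floor of 3 counts and at least 25.4-fold by the lower bound of its counting interval. Among 9 measured genes listed as Wnt targets before their values were seen, Nkd2 was higher at 1.76 and 0 were lower, with a median of -0.16 and a mean of 0.18. Whether each of the 9 is a Wnt target in these cells was not determined. The percentile of 6.96 missed the required 2.5, and the members spread from -0.62 to 1.76, so that the test decided nothing, by the reading that was changed in the same way after the value was seen. Axin2, a widely used Wnt readout, stood at 0.94 on the log2 scale, in the direction opposite to the hypothesis.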
